A study of Mus musculus with 8 samples.

How the data were processed

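Total RNA of mouse 3T3-L1 preadipocytes was sequenced by the authors in 8 samples, 4 with control siRNA and 4 with Fto siRNA, per the labels. Each group had received a pool of 3 Stealth siRNAs (chemically modified duplexes) at 40 nM in a lipid reagent for 24 hours before the cells reached confluence, and the cells were collected 2 days past confluence. Reads were aligned with TopHat2 2.0.11 and quantified with Cufflinks 2.2.1 on genome build mm9, per the submitters' processing notes. The deposited FPKM (fragments scaled by transcript length and by the number of mapped fragments) came as 1 table per library with Cufflinks intervals and a status, per the file headers. The authors also compiled the FPKM into an included table of 23404 genes and an excluded table of 292, with their means and SDs, fold changes of the means and p-values, per the file headers. The deposited fold is a linear ratio of Fto siRNA over control siRNA, and the deposited p-value is that of a t-test, per the file headers, whose variance and sidedness are not given in the sources used here. Whether the libraries kept strand is not given in the sources used here, so reads of overlapping genes cannot be told apart. FPKM divides by transcript length and library size and is shared among genes by the Cufflinks model, so it holds no counts, and genes with near-identical copies can exchange signal.

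Depth was worked out from the deposited FPKM and intervals as the number of fragments that gives each interval its width. This gave 18.9 to 24.4 M fragments per library, a relative depth of 0.902 to 1.16, and whole numbers within 0.02 for 72.8% of low values. No count test was run, because FPKM are not counts. The intervals cover counting error only. The FPKM of a library summed to 454737 to 484842, of which the 20 highest genes held 10.7 to 11.8%. Pairs of libraries within a group differed by a median of 0.895 to 1.53 standard errors, so none was treated as a library deposited again. Control replicate 3 stood furthest from its group. Its pairs with the other controls had medians of 1.28 to 1.53 standard errors, against 0.895 to 0.98 for pairs among the other controls. The labels do not say whether replicates are separate cultures, so p-values measure only the spread between these samples, which can be technical.

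The tested value was log2(FPKM + 0.5) for genes with a mean FPKM of at least 1 over the 8 libraries, 11398 genes. A fold change is on that scale, which understates the change of low genes. Groups were compared with limma 3.58.1 (R 4.3.3) with a trend in the prior variance, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Adjusted p are from limma except for the permutation tests. The tests, the alternatives, 33 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members, 31 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list with the other genes, and again with a correlation estimated from the libraries. For Fto and for list means per library an exact two-sided permutation test was run, and a Benjamini-Hochberg adjustment over the 31 lists was added after the data were seen. The smallest p of the permutation test, 0.0286, is too large for a list to pass that adjustment alone, whatever its effect. The rule named Fto, the 12 largest rises and 12 largest falls among called genes with a mean FPKM of at least 2, 1 entry per symbol and no overlap between groups, up to 4 members per list with the lowest p, and 19 genes of the adipogenesis and RNA methylation fields whatever their values. Of the deposited entries, 248 symbols occurred more than once, and 25 symbols were written as dates, of which 16 were tested and none is named. Some genes that the rule names are not reported here.

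Loci of genes are as deposited, in mm9, counted from 1. Transcript sequences came from the GENCODE M21 annotation of GRCm38, which was used for sequence only. Annotated 3′ UTRs of at least 50 bases were searched over their first 5000 bases for 16178 words of 7 bases in 9634 tested genes. For this search extreme log2 fold changes were capped, and the values were adjusted by regression for UTR length, base composition and mean FPKM. A z value compared the mean adjusted value of the carriers of each word with that of all searched genes. A gene is said to hold a word where its whole 3′ UTR does. Neighbourhoods were compared through runs of adjacent tested genes. These steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9. On 5 simulated sets with 200 changed genes among 11398, the test recovered a median of 59% (53 to 65) of genes changed by 0.3 and 94% (90 to 95) of genes changed by 0.6 on the log2 scale. It made 5 to 32 calls among unchanged genes. Camera called 0 lists in sets with no effect, which was fixed in advance, since those sets held no difference between the groups even by chance.

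Alternatives were pseudocounts of 0.1 and 1, no filter or a minimum mean FPKM of 5, median-ratio and quantile scaling, no trend, sample weights, a replicate block, a minimum fold of 1.2, the authors' included genes only, an estimated correlation for lists, and each library left out in turn. Added after the data were seen were genes with an OK status in all libraries, genes without the words GACCTTA and ACCTTAA in the 3′ UTR, and the latter also without control replicate 4.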

Results

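Gene expression was measured by RNA sequencing in 3T3-L1 cells, a mouse fibroblast line that can differentiate into adipocytes. The cells were preadipocytes at 2 days past confluence that had received siRNAs against Fto or non-targeting siRNAs. Fto encodes a dioxygenase of the AlkB family that removes methyl groups from RNA and DNA. The comparison asks which transcripts differ once Fto mRNA is lowered in cells that have not yet been induced to differentiate. There were 4 libraries per group, and all means and SDs below are over n = 4. Each library listed FPKM for 23699 genes, with 11351 to 11397 genes at 1 FPKM or more. The depth worked out from the deposited intervals was 18.9 to 24.4 M fragments per library, and the median upper interval bound lay 6.57 to 7.52% above the value. The first principal component of the tested genes held 27.5% of the variance and placed the controls between -13.8 and -9.41 and the Fto siRNA libraries between 7.88 and 12.8.

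Fto mRNA was lower in each of the 4 libraries with Fto siRNA than in each control. Its locus in the deposited files is mm9 chromosome 8, 93837424 to 94192332. The controls held 54.6, 55.4, 56.2 and 55.2 FPKM, a mean of 55.3 ± 0.647 (SD, n = 4). The Fto siRNA libraries held 13.8, 10.7, 12.3 and 11.6 FPKM, a mean of 12.1 ± 1.29 (SD, n = 4), which is 78.1% below the control mean. The log2 fold change was -2.15 with SE 0.063 (limma adjusted p = 7.3e-08). An exact two-sided permutation test of the FPKM gave p = 0.0286, the smallest that 70 arrangements allow. In the authors' deposited table the Fto fold was 0.22 with a Bonferroni-corrected p-value of 3.43e-05.

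**Figure D1:**
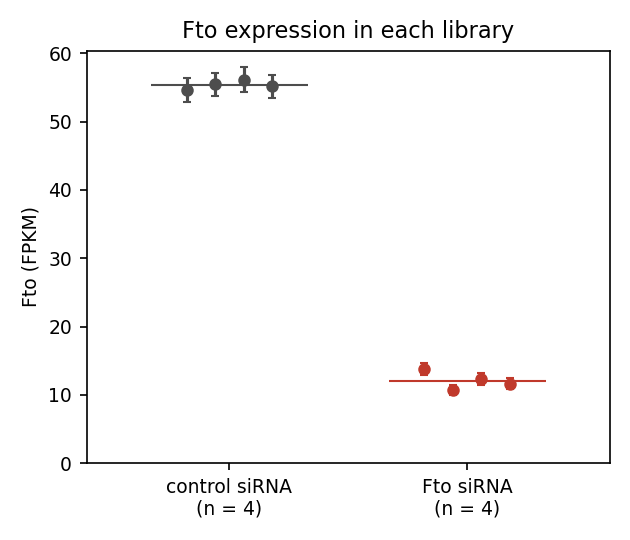
Fto expression in FPKM (vertical axis, linear from 0) in each control siRNA and Fto siRNA library, n = 4 per group; points are libraries, bars are the deposited Cufflinks intervals and horizontal lines are group means. The Fto siRNA libraries lie between 10.7 and 13.8 FPKM and the controls between 54.6 and 56.2 FPKM.

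Beyond Fto, the rises with the largest fold included those of Klf2, Pi16, Rhob and Wnt4. Klf2, a Krüppel-like transcription factor, rose from 4.27 ± 0.720 to 11.2 ± 0.481 FPKM (SD, n = 4), a log2 fold change of 1.31 (limma adjusted p = 2.1e-05). Pi16, a marker of fibroblast progenitors, rose from 2.66 ± 0.549 to 6.65 ± 0.769 FPKM (log2 fold change 1.19, adjusted p = 2.5e-04). Rhob, a small GTPase, rose from 24.0 ± 0.740 to 49.4 ± 3.54 FPKM (log2 fold change 1.03, adjusted p = 2.5e-06), and the secreted ligand Wnt4 rose from 3.80 ± 0.187 to 8.14 ± 0.245 FPKM (1.01, adjusted p = 2.8e-06). Hist1h4i, a histone H4 gene, rose from 5.55 ± 0.779 to 11.4 ± 0.977 FPKM, and Agt, which encodes angiotensinogen, from 29.5 ± 4.58 to 52.9 ± 5.97 FPKM. The membrane protein genes Gpr155 and Tusc5 rose by log2 fold changes of 0.92 and 0.85, the galectin gene Lgals7 by 0.86, the phosphatase gene Ptprv by 0.83 and the host transcript Snhg10 by 0.91. Snora74a, a small nucleolar RNA, was listed at 0 in the 4 controls and at 6.24, 10.7, 2.39 and 2.08 FPKM in the Fto siRNA libraries. The Snora74a locus lies inside that of Snhg4, and that of Snhg10 overlaps Mir3069 and Scarna13, so reads of these genes cannot be told apart.

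The falls with the largest fold after that of Fto included those of Ces1a, Adi1 and Clca1. Ces1a, a carboxylesterase, fell from 5.90 ± 0.418 to 2.32 ± 0.355 FPKM (SD, n = 4), a log2 fold change of -1.19 (limma adjusted p = 4.3e-05). Adi1, an enzyme of methionine salvage, fell from 32.1 ± 1.46 to 14.6 ± 1.05 FPKM (-1.11, adjusted p = 2.5e-06), and Clca1 from 217 ± 11.9 to 104 ± 7.76 FPKM (-1.06, adjusted p = 4.4e-06). Thbs2, a thrombospondin of the matrix, fell from 279 ± 13.3 to 151 ± 9.01 FPKM, and Marcks, a substrate of protein kinase C, from 330 ± 22.1 to 178 ± 4.62 FPKM. Plac8 fell from 196 ± 19.3 to 107 ± 6.63 FPKM, the phospholipid acyltransferase Lpcat2 from 5.83 ± 0.243 to 2.74 ± 0.231 FPKM, the hormone gene Insl3 from 6.26 ± 1.57 to 2.72 ± 0.933 FPKM and the circadian repressor Nr1d2 from 7.05 ± 0.428 to 3.63 ± 0.181 FPKM. The interferon-induced genes Ifit1, Ifit3 and I830012O16Rik, an older name of Ifit3b, fell by log2 fold changes of -1.01, -1.01 and -1.02. Ifit1 was not called when Fto siRNA replicate 1 was left out (log2 fold change -0.96, limma adjusted p = 0.0503) or with no filter on low values (0.0599). Ces1a, Clca1 and the Ifit genes have close paralogs between which reads can be split, and the loci of Insl3 and Lpcat2 overlap Jak3 and Capns2.

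Across 11398 tested genes, limma called 794 that rose and 1401 that fell at the adjusted threshold of 0.05. A fold of at least 1.5 was reached by 50 of the risen and 66 of the fallen genes, and a fold of at least 2 by 9 and 12. The groups did not overlap for 1035 higher and 1726 lower genes, where chance gives 2.86% of genes. With median-ratio scaling the counts were 1086 and 1218 and with quantile normalization 1086 and 1207, so risen genes made up 47.1% and 47.4% of calls against 36.2%. The words GACCTTA and ACCTTAA were picked as those whose carriers had the lowest z in these data, so their share among fallen genes is no separate test. Their z was -16.9 and -13.3, against a largest absolute z of 5.34 in 100 shuffles of the fold changes. Of the fallen genes with a searched 3′ UTR, 306 of 1219 (25.1%) held GACCTTA or ACCTTAA there, against 46 of 692 risen genes (6.65%) and 765 of 7723 others (9.91%). Adi1, Thbs2 and Marcks hold the joined word GACCTTAA, and Klf2, which rose, holds a shorter form. GACCTTAA occurs once in the Fto coding sequence, at GRCm38 chromosome 8, 91409664 to 91409671, in exon 3 of 9. The siRNA sequences are not given in the sources used here. Mir686 and Snora24, named after their values were seen, were also called lower, from 24.2 ± 26.7 and 16.5 ± 13.8 FPKM in the controls, but no library listed them with an OK status.

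**Figure D2:**
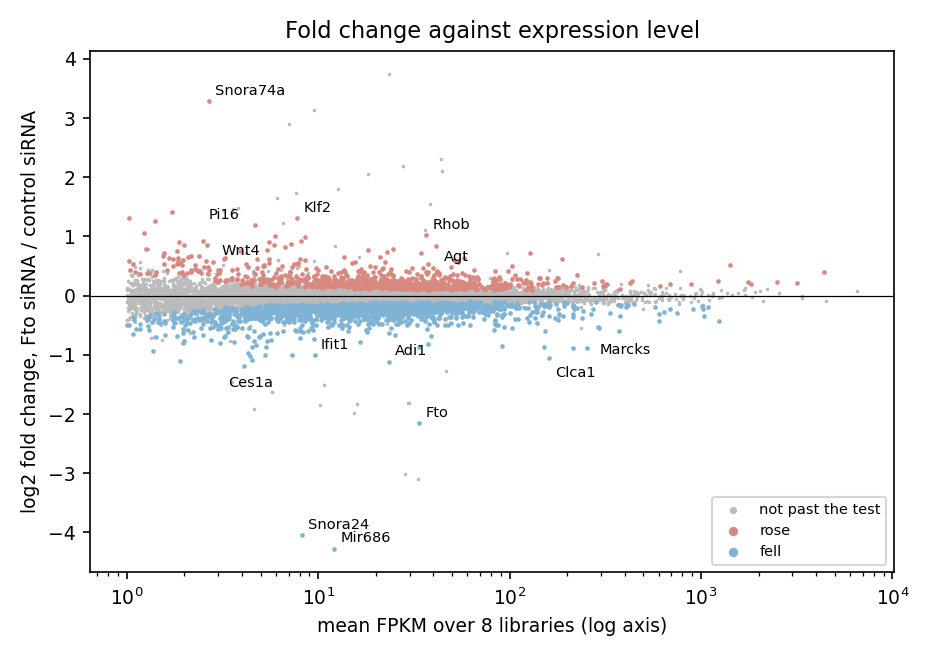
Log2 fold change of Fto siRNA over control siRNA (vertical axis) against mean FPKM over the 8 libraries (horizontal log axis) for 11398 genes, with risen genes in red, fallen genes in blue and the rest in grey. The called genes lie mostly close to 0, with Fto at -2.15 and Klf2 at 1.31 among the largest.

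Most other enzymes and readers of nucleic acid methylation did not pass the test. In the AlkB family, Alkbh6 fell beside Fto, from 16.8 ± 1.18 to 14.2 ± 0.621 FPKM (SD, n = 4; log2 fold change -0.23, limma adjusted p = 0.014), and 7 of 9 members did not pass. The RNA demethylase Alkbh5 held 23.3 ± 0.287 and 24.5 ± 0.712 FPKM (log2 fold change 0.07, adjusted p = 0.18). Of 22 writers and readers of RNA m6A, 3 fell and 19 did not pass: the reader Igf2bp2 fell by 0.18 on the log2 scale (adjusted p = 0.0047), Rbm15b by 0.15 and Mettl16 by 0.14. The methyltransferase subunits Mettl3, Mettl14 and Wtap had log2 fold changes of -0.08, -0.08 and 0.01 and the reader Ythdf2 -0.01, with adjusted p of 0.26, 0.29, 0.88 and 0.93. Among 13 enzymes of DNA adenine and cytosine methylation, Dnmt3a rose by 0.25 (adjusted p = 0.0094) and Mettl4 fell by 0.27 on the log2 scale (adjusted p = 0.019). Adjusted over the list alone, 2 AlkB genes fell, 2 m6A genes fell, and 1 DNA methylation gene rose and 1 fell. The list medians were -0.07, -0.06 and 0.00, with camera adjusted p of 0.479, 0.464 and 0.479. Rbm15b was not called without control replicate 1, 2 or 4 or Fto siRNA replicate 2, 3 or 4 (adjusted p 0.0529 to 0.0654), Mettl16 without any library but control replicate 3 (0.0543 to 0.107) and Mettl4 without control replicate 2 or Fto siRNA replicate 4 (0.0528 and 0.0542). The 3′ UTRs of Mettl3, Mettl14, Mettl16 and Mettl4 hold GACCTTA or ACCTTAA, and the loci of Mettl3 and Dnmt3a overlap Tox4 and Gm10485.

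Genes next to Fto did not pass the test, and a group of genes more than 1 Mb downstream fell. Rpgrip1l, a cilium gene that borders Fto, held 8.10 ± 0.444 and 7.82 ± 0.549 FPKM (SD, n = 4; log2 fold change -0.05, limma adjusted p = 0.62), and Rbl2, a pocket protein gene, had a log2 fold change of -0.10 (adjusted p = 0.066). The homeobox genes Irx3 and Irx5 held 3.81 ± 0.464 and 5.95 ± 0.630 FPKM in the controls, with log2 fold changes of -0.21 (adjusted p = 0.117) and -0.13 (adjusted p = 0.23). Mmp2, a gelatinase, fell from 745 ± 12.6 to 639 ± 22.7 FPKM (-0.22, adjusted p = 0.0037), and Lpcat2 fell by 0.97 on the log2 scale. Of the 8 listed neighbours 2 fell and 6 did not pass, and 3 fell when adjusted over the list alone (median -0.11, camera adjusted p = 0.0629; 0.048 without control replicate 3 and 0.0459 without Fto siRNA replicate 3). Of all 14 tested genes within 2 Mb, 5 fell and 9 did not pass: Mmp2, Lpcat2, Ces1a and, named after their values were seen, Capns2 (-0.77) and Ces1d (-1.11). Their paralogs Ces1f and Ces1g in the same cluster had log2 fold changes of 0.06 and 0.10, adjusted p = 0.65 and 0.42. The median over the 14 genes was -0.17, at or below which lay 0.558% of 11110 overlapping runs of as many neighbouring genes elsewhere. The 3′ UTRs of Mmp2 and Irx3 hold GACCTTA or ACCTTAA, and Capns2 lies inside Lpcat2. Without those carriers and Capns2 the median of 11 genes was -0.10, reached by 6.04% of runs; all 3 lay below the median of the 14, so their removal had to raise it. Rbl2 overlaps Aktip.

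**Figure D3:**
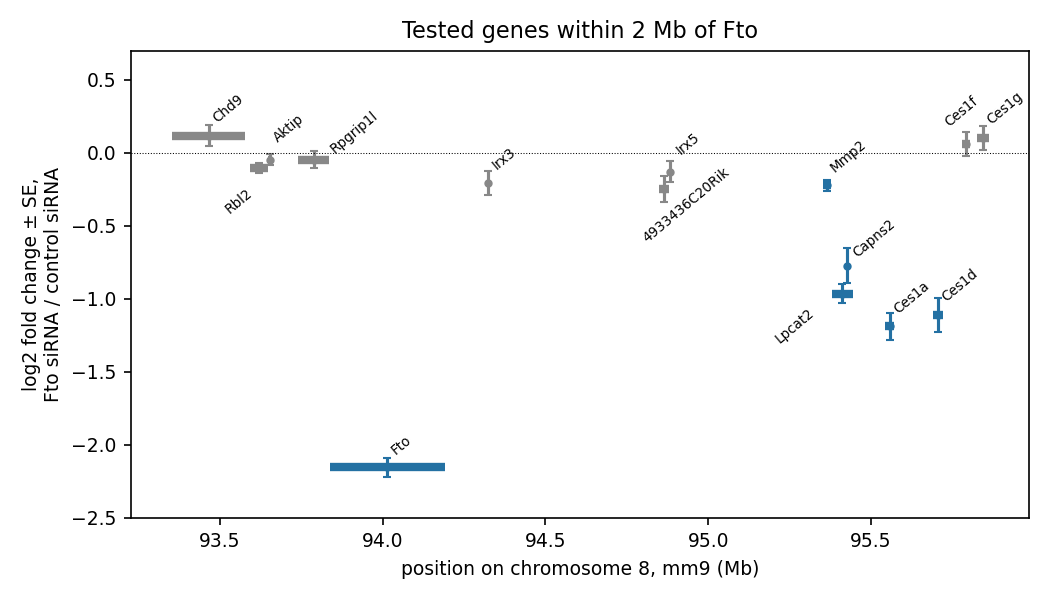
Log2 fold change of Fto siRNA over control siRNA (vertical axis, bars are ± SE) of Fto and the 14 tested genes within 2 Mb, against position on mm9 chromosome 8 in Mb (horizontal axis, thick lines span each gene); blue marks genes that fell and grey those that did not pass. Lpcat2, Capns2, Ces1a and Ces1d lie between -0.77 and -1.19, while Rpgrip1l and Aktip next to Fto lie at -0.05.

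Regulators of adipocyte differentiation changed in both directions, while the central receptor gene Pparg did not pass the test. Pparg, the nuclear receptor that drives adipogenesis, held 32.9 ± 0.929 FPKM in the controls and 32.6 ± 1.96 FPKM with Fto siRNA (SD, n = 4; log2 fold change -0.01, limma adjusted p = 0.86). Cebpa, its partner, rose from 8.45 ± 1.47 to 11.5 ± 0.994 FPKM (0.44, adjusted p = 0.019), while Cebpb and Cebpd had log2 fold changes of 0.04 (adjusted p = 0.80) and -0.06 (adjusted p = 0.71). Runx1t1, counted here among the inhibitors of adipogenesis, fell from 13.3 ± 0.474 to 10.9 ± 0.974 FPKM (-0.27, adjusted p = 0.011), and FPKM per gene do not separate isoforms. Of 25 early regulators 5 rose and 2 fell, with Klf4 at 0.30, Nr3c1 at 0.16, Ebf1 at -0.23 and Plac8 at -0.87. Of 24 inhibitors 5 rose and 6 fell, with Klf2 at 1.31, the glucocorticoid-induced gene Tsc22d3 at 0.57 (adjusted p = 1.7e-05), Wisp2 at -0.46 and Hes1 at -0.38. Dlk1, a preadipocyte inhibitor of differentiation, held 918 ± 78.6 and 939 ± 51.2 FPKM (log2 fold change 0.03, adjusted p = 0.76), and Foxo1 had -0.16 (adjusted p = 0.056). Adjusted over the list alone, 5 early regulators rose and 3 fell, and 5 inhibitors rose and 7 fell. The camera adjusted p were 0.249 and 0.756, and the inhibitors had a median of -0.01 but a mean of 0.04 and a test direction of up. Cebpa was not called without control replicate 2 (adjusted p = 0.0509) or Fto siRNA replicate 4 (adjusted p = 0.0565), nor with no filter on low values (0.0602). The 3′ UTR of Foxo1 holds GACCTTAA, and the Cebpd locus overlaps 2310008H04Rik.

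Fibroblast markers changed in both directions, and genes of mature fat cells fell or did not pass. Ly6a, the stem cell antigen Sca-1, rose from 147 ± 5.04 to 227 ± 15.02 FPKM (SD, n = 4; log2 fold change 0.63, limma adjusted p = 4.3e-05). The matrix gene Dpt rose from 96.1 ± 12.2 to 159 ± 14.3 FPKM (0.73, adjusted p = 5.0e-04), and the hyaluronan receptor gene Cd44 rose by 0.37. Of 19 preadipocyte and fibroblast markers 7 rose and 5 fell, and 9 and 5 did when adjusted over the list alone (median 0.05, camera adjusted p = 0.0861). The 5 that fell, named after their values were seen and not recomputed under the alternatives, were Lox (-0.27), F3 (-0.26), Ptx3 (-0.21), Pdgfra (-0.21) and Pdgfrb (-0.14), with adjusted p of 0.0012 to 0.025, and the 3′ UTRs of Lox and Pdgfra hold GACCTTA or ACCTTAA. The lipoprotein lipase gene Lpl, whose 3′ UTR holds GACCTTA or ACCTTAA, fell from 368 ± 8.09 to 301 ± 10.3 FPKM (-0.29, adjusted p = 5.9e-04). Acsl1 and Dgat1, enzymes of fatty acid activation and triglyceride synthesis, fell by 0.43 and 0.20 on the log2 scale and the lipase gene Lipe by 0.22. Of 18 mature adipocyte genes 4 fell and 14 did not pass, and 4 fell when adjusted over the list alone (median -0.15, camera adjusted p = 0.103). The mean log2 value over that list was 3.24, 3.41, 3.36 and 3.62 in controls 1 to 4 and 3.20 to 3.25 with Fto siRNA, a difference of -0.18 (exact permutation p = 0.0857, adjusted p = 0.190 over 31 lists). Without control replicate 4, the highest, the difference was -0.11 (camera adjusted p = 0.271), and control replicate 1 lay level with the Fto siRNA libraries. Without control replicate 1 or 3 the camera adjusted p was 0.0461 or 0.048. Lipe, whose locus overlaps 4732471J01Rik, was not called without any library but control replicate 1 (adjusted p 0.0584 to 0.0971). The leptin receptor gene Lepr lay below the filter, at 0.117 and 0.101 FPKM.

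Cyclin D1 and the p53 target Cdkn1a rose, and most genes of DNA replication and mitosis did not pass. Ccnd1 rose from 139 ± 3.09 to 157 ± 1.97 FPKM (SD, n = 4; log2 fold change 0.17, limma adjusted p = 0.0037), while Ccna2 and Cdk2 had log2 fold changes of -0.06 each (adjusted p = 0.64 and 0.43). Cdkn1a, an inhibitor of cyclin-dependent kinases, rose from 107 ± 5.42 to 140 ± 5.70 FPKM (0.39, adjusted p = 4.3e-04), and the stress genes Gadd45a, Trp53inp1 and Aen rose by 0.40, 0.27 and 0.20. Of 26 cell cycle inhibitors and p53 targets 7 rose and 2 fell, and 9 and 3 did when adjusted over the list alone (median 0.03, camera adjusted p = 0.0629; 0.0431 without control replicate 3 and 0.0363 without Fto siRNA replicate 1). Of 33 genes of DNA replication and G1 to S, Rrm2, Ccne1 and Rrm1 rose by 0.28, 0.27 and 0.10, Tyms fell by 0.26 on the log2 scale and 29 did not pass. Adjusted over the list alone 1 rose (median 0.04, camera adjusted p = 0.114; 0.0137 without Fto siRNA replicate 3). Among 39 genes of G2 and M phase limma called 0 higher and 0 lower, also adjusted over the list alone, with 2 higher and 4 lower at an unadjusted p under 0.05. Their median was 0.01 (camera adjusted p = 0.619), with Tpx2 at 0.13 (adjusted p = 0.11) and Cenpa at -0.13 (adjusted p = 0.058). Ccne1 was not called without control replicate 2 or Fto siRNA replicate 2 or 4 (adjusted p 0.0508 to 0.0657), Tyms without control replicate 1, 3 or 4 or Fto siRNA replicate 2, 3 or 4 (0.0630 to 0.114) and Rrm1 without any 1 of the 8 libraries (0.0561 to 0.0974). The loci of Gadd45a and Ccna2 overlap E230016M11Rik and Exosc9, and the 3′ UTRs of Rrm2 and Tpx2 hold GACCTTA or ACCTTAA.

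Histone genes were higher as a list at the preset correlation (camera adjusted p = 0.0025), but not with an estimated correlation (adjusted p = 0.629). Of 13 tested histone genes 7 rose, 1 fell and 5 did not pass, and 7 and 1 passed when adjusted over the list alone. Hist1h4i rose by 0.98 (limma adjusted p = 1.2e-04), Hist1h2be from 1.19 ± 0.174 to 2.13 ± 0.314 FPKM (SD, n = 4; log2 fold change 0.64) and Hist2h3c1 from 9.04 ± 0.519 to 12.96 ± 2.08 FPKM (0.49). H2afx, the variant H2A.X of the DNA damage response, fell from 21.7 ± 2.28 to 15.6 ± 1.33 FPKM (-0.46, adjusted p = 0.0037), and its 3′ UTR holds GACCTTA or ACCTTAA. The list median was 0.30. With a filter of mean FPKM of at least 5 the camera adjusted p was 0.0507. Of the 35 splits of the 8 libraries, 4 gave this list a test at least as strong, the real one included. The mean log2 value over the list was 3.30 to 3.52 in the controls and 3.61 to 3.90 with Fto siRNA (exact permutation p = 0.0286, adjusted p = 0.0984 over 31 lists). Histone genes are near-identical copies between which reads can be split, and Hist1h2be overlaps Hist1h1e.

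Genes of the matrix changed in both directions, and several proteases of the matrix fell. Col5a3, a chain of type V collagen, rose from 35.9 ± 0.945 to 47.4 ± 1.95 FPKM (SD, n = 4; log2 fold change 0.40, limma adjusted p = 1.4e-04), and Fbln1 rose by 0.42, while Thbs2 fell by 0.89 and Spp1, osteopontin, by 0.45 on the log2 scale. Of 33 collagen and matrix genes 11 rose and 5 fell, and 14 and 8 did when adjusted over the list alone (median 0.09, camera adjusted p = 0.202). Mmp14, a membrane-bound collagenase, fell from 344 ± 10.3 to 238 ± 14.4 FPKM (-0.53, adjusted p = 8.6e-05), Plau, the urokinase gene, fell by 0.75 and Mmp23 by 0.38 on the log2 scale, and the gelatinase gene Mmp9 rose by 0.32. Of 19 metalloproteinases and inhibitors 4 rose and 7 fell, and 5 and 8 did when adjusted over the list alone (median -0.04, camera adjusted p = 0.249). Of 13 basement membrane genes 3 rose and 3 fell, the same numbers as when adjusted over the list alone, with Col15a1 at 0.40, Npnt at 0.38, Nid2 at 0.21 and Lama4 at -0.21. That list had a median of -0.05 but a mean of 0.05 and a test direction of up (camera adjusted p = 0.688). Npnt was not called without Fto siRNA replicate 2 (adjusted p = 0.0508), and Nid2 without control replicate 2 or 4 or Fto siRNA replicate 1 or 4 (0.0593 to 0.0709). The 3′ UTR of Mmp14 holds GACCTTA or ACCTTAA, and Nid2 overlaps 2700060E02Rik.

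TGF-beta and Wnt genes had list medians near 0 with single members past the test. The contractile genes Cnn2 and Tpm1 fell from 421 ± 19.3 to 332 ± 7.05 FPKM and from 671 ± 28.6 to 543 ± 15.6 FPKM (SD, n = 4; log2 fold changes -0.34 and -0.30, limma adjusted p = 4.5e-04 and 9.8e-04), Amotl2 fell by 0.23 and the integrin gene Itga5 rose by 0.20. Of 28 TGF-beta targets and contractile genes 2 rose and 4 fell, as when adjusted over the list alone (median 0.01, camera adjusted p = 0.776). The Wnt co-receptor gene Lrp5 rose from 56.8 ± 1.601 to 67.6 ± 1.86 FPKM (0.25, adjusted p = 9.8e-04), and Ccnd1, Myc and Wnt6 rose by 0.17, 0.18 and 0.34. Of 17 Wnt components and targets 4 rose and 1 fell, as when adjusted over the list alone, with a median of -0.00, a mean of 0.03 and a test direction of up (camera adjusted p = 0.277). Wnt6 was not called without control replicate 4 (adjusted p = 0.0552) or Fto siRNA replicate 4 (adjusted p = 0.0573).

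Interferon-stimulated genes were lower after Fto siRNA, in a list in which control replicate 4 stood above the other controls. The list was called at the preset correlation (camera adjusted p = 1.2e-10), but not with an estimated correlation (adjusted p = 0.629). Of 39 tested members 26 fell and 13 did not pass, 32 fell when adjusted over the list alone, and all 39 had a negative log2 fold change, with a median of -0.47. Ifit1 held 14.97, 7.98, 9.57 and 20.1 FPKM in controls 1 to 4 and 5.24, 7.62, 5.70 and 5.28 FPKM in Fto siRNA libraries 1 to 4. B2m, the light chain of MHC class I, fell from 1428 ± 145 to 1060 ± 61.2 FPKM (SD, n = 4; log2 fold change -0.43, limma adjusted p = 0.0034), and H2-K1, a class I heavy chain, fell by 0.49 on the log2 scale. Parp14 and the RNA sensor gene Dhx58 fell by 0.60 and 0.76. Control replicate 4 was the highest control for 36 of the 39 genes, and for 26 every control lay above every Fto siRNA library. The mean log2 value over the list was 3.53, 3.32, 3.39 and 3.91 in controls 1 to 4 and 3.00, 3.15, 3.01 and 3.03 with Fto siRNA (exact permutation p = 0.0286, the smallest possible; adjusted p = 0.0984 over 31 lists). Without control replicate 4 the median was -0.36. Of the 35 splits of the 8 libraries, 9 gave this list a test at least as strong, the real one included. The 3′ UTR of Parp14 holds GACCTTA or ACCTTAA, B2m overlaps Patl2, and H2-K1 has close paralogs.

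**Figure D4:**
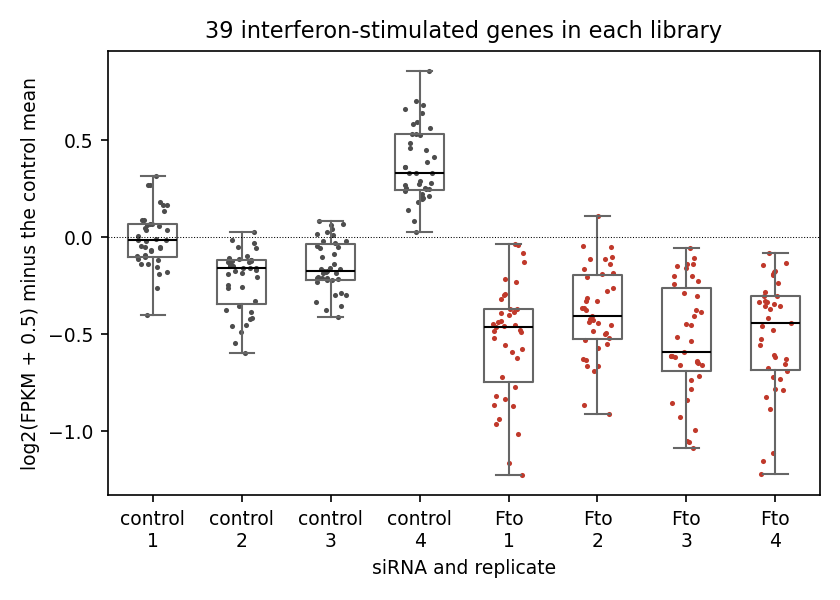
Log2(FPKM + 0.5) minus the control mean (vertical axis) of 39 interferon-stimulated genes in each of the 8 libraries (horizontal axis); points are genes, boxes are quartiles with the median, and whiskers span the range. Control replicate 4 is the highest control for 36 genes, and the 4 Fto siRNA medians lie below the 4 control medians.

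Of the inflammatory genes outside the interferon response more fell than rose, and the list was not called. The chemokine gene Cxcl12 fell from 1166 ± 85.3 to 918 ± 32.5 FPKM (SD, n = 4; log2 fold change -0.34, limma adjusted p = 0.0025), and Ccl2 from 165 ± 5.21 to 131 ± 10.6 FPKM (-0.33, adjusted p = 0.0026). The protease gene Mmp3 and the transcription factor gene Nfkb1 fell by 0.23 and 0.12 on the log2 scale. Of 23 NF-kB and inflammatory genes 2 rose and 8 fell, and 4 and 9 did when adjusted over the list alone (median -0.01, camera adjusted p = 0.759). The 3′ UTR of Cxcl12 holds GACCTTA or ACCTTAA.

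Genes of cholesterol synthesis and of the unfolded protein response were higher as lists, by small folds, at the preset correlation (camera adjusted p = 0.0031 and 0.0050), but not with an estimated correlation (adjusted p = 0.629 for both). Srebf2, the transcription factor of sterol synthesis, rose from 47.5 ± 0.874 to 54.7 ± 1.78 FPKM (SD, n = 4; log2 fold change 0.20, limma adjusted p = 0.0028). Dhcr7, a late enzyme of the pathway, rose from 17.3 ± 0.558 to 20.5 ± 1.61 FPKM (0.24, adjusted p = 0.013), and Sqle rose by 0.19. Of 23 cholesterol genes 5 rose and 18 did not pass, and 5 rose when adjusted over the list alone (median 0.08). Of 30 genes of the unfolded protein response and amino acid stress 11 rose and 3 fell, and 12 and 4 did when adjusted over the list alone. The degradation factor Edem1 rose by 0.27 (adjusted p = 0.0011), the transcription factor Cebpg by 0.24 and the mitochondrial folate enzyme Mthfd2 by 0.40, while the chaperone Calr fell from 980 ± 24.7 to 839 ± 22.6 FPKM (-0.22). The stress list had a median of 0.11. Of the 35 splits of the libraries, 11 gave the cholesterol list and 10 the stress list a test at least as strong, the real one included. Sqle was not called without control replicate 1 or 4 or Fto siRNA replicate 1, 2 or 4 (adjusted p 0.0524 to 0.0606), and the Srebf2 locus holds Mir33.

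Among other metabolic genes, single genes of fatty acid oxidation and metallothioneins fell and the angiogenic factor Vegfa rose. Hadhb, a subunit of the mitochondrial trifunctional protein, fell from 18.9 ± 0.910 to 13.4 ± 0.454 FPKM (SD, n = 4; log2 fold change -0.48, limma adjusted p = 1.1e-04), the carnitine carrier gene Slc25a20 fell by 0.29 on the log2 scale, and Esrra rose by 0.20. Of 23 genes of fatty acid oxidation and mitochondrial biogenesis 2 rose and 3 fell, as when adjusted over the list alone (median -0.06, camera adjusted p = 0.479). Among 38 nuclear genes of oxidative phosphorylation limma called 0 higher and 0 lower, also adjusted over the list alone, with 0 higher and 1 lower at an unadjusted p under 0.05. Their median was -0.00, their mean 0.01 and the test direction up (camera adjusted p = 0.479; 0.048 without control replicate 3), with Cox7b, whose 3′ UTR holds GACCTTA or ACCTTAA, at -0.18 (adjusted p = 0.055) and Atp5b at 0.09 (adjusted p = 0.16). Vegfa rose from 40.9 ± 3.92 to 57.6 ± 2.62 FPKM (0.49, adjusted p = 6.9e-04), Pfkp and P4ha1 rose by 0.28 and 0.19, and the vasodilator gene Adm fell from 48.0 ± 1.94 to 27.0 ± 1.76 FPKM (-0.82, adjusted p = 8.2e-06). Of 26 glycolysis and hypoxia genes 5 rose and 2 fell, and 6 and 2 did when adjusted over the list alone (median 0.08, camera adjusted p = 0.0629; 0.0431, 0.0224 and 0.0131 without control replicate 3, control replicate 4 and Fto siRNA replicate 2). The metallothionein genes Mt1 and Mt2 fell by 0.59 and 0.44, the peroxiredoxin gene Prdx6 by 0.32 and Gstm1 by 0.35 on the log2 scale. Of 28 oxidative stress and NRF2 targets 2 rose and 8 fell, and 3 and 10 did when adjusted over the list alone (median -0.02, camera adjusted p = 0.619). The 3′ UTR of Hadhb holds GACCTTAA. Esrra was not called without control replicate 1, 2 or 4 or Fto siRNA replicate 1 or 4 (adjusted p 0.0825 to 0.0920). The loci of Hadhb, Esrra and Pfkp overlap Mir1960, Trmt112 and Pitrm1.

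Growth factor signalling and immediate early genes held single changes of known regulators. Pik3r1, a PI3 kinase subunit, rose from 37.1 ± 1.82 to 44.2 ± 1.79 FPKM (SD, n = 4; log2 fold change 0.25, limma adjusted p = 0.0039), Igfbp6 rose by 0.41, and Igf2 fell by 0.26 on the log2 scale. Of 26 insulin, IGF and mTOR genes 2 rose and 2 fell, as when adjusted over the list alone (median 0.02, camera adjusted p = 0.285). Jun, a subunit of AP-1, rose from 28.7 ± 1.09 to 37.0 ± 1.43 FPKM (0.36, adjusted p = 3.6e-04), and of 26 immediate early genes, which include Klf2, Rhob and Klf4, 5 rose and 2 fell, as when adjusted over the list alone (median 0.03, camera adjusted p = 0.0876; 0.048 without control replicate 3). Of 23 primary cilium and hedgehog genes 1 rose and 2 fell, with Gli2 at 0.21 and Bbs2 at -0.18, and 1 rose and 2 fell when adjusted over the list alone (median -0.10, camera adjusted p = 0.155). The Igf2 locus overlaps Igf2as and Mir483.

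Markers of other cell types were few among the tested genes, and few genes of translation and RNA interference passed the test. Of 3 tested macrophage, leukocyte, endothelial and epithelial markers Lyz2, lysozyme, fell from 16.7 ± 2.38 to 11.6 ± 0.492 FPKM (SD, n = 4; log2 fold change -0.50, limma adjusted p = 0.0032), Cd68 and Cd14 did not pass at 0.21 and 0.07, and 1 fell when adjusted over the list alone. Their median was 0.07 and their mean -0.07, with too few members for a list test. Of 4 osteoblast and chondrocyte markers Spp1 and Runx2 fell by 0.45 and 0.13 on the log2 scale, Comp and Sox9 did not pass at -0.23 and 0.09, and 3 fell when adjusted over the list alone (median -0.18, not tested as a list). Of 5 muscle markers Lmod1 fell by 0.31 and 4 did not pass, and 1 rose and 1 fell when adjusted over the list alone. That list had a median of -0.06 and a mean of -0.05 but a test direction of up (camera adjusted p = 0.937). Of 35 cytosolic ribosomal protein genes Rpl4, Rpl27 and Rpl5 fell by 0.22, 0.15 and 0.12 on the log2 scale, Rpl22 rose by 0.14, and 1 fell when adjusted over the list alone (median 0.01, camera adjusted p = 0.850). Of 13 genes of RNA interference Adar, an RNA editing enzyme that interferon induces, fell by 0.26 (adjusted p = 0.038), 12 did not pass, and adjusted over the list alone limma called 0, against 1 at an unadjusted p under 0.05 (median -0.02, camera adjusted p = 0.938). Adar and Runx2 were not called without any library but control replicate 3 (adjusted p 0.0528 to 0.1004) and control replicate 4 (0.0565 to 0.109). Rpl27 and Rpl5 were not called without any library but control replicate 1 (0.0534 to 0.106 and 0.0586 to 0.117), and Rpl22 without control replicate 1, 2 or 4 or Fto siRNA replicate 2, 3 or 4 (0.0826 to 0.122). The 3′ UTR of Sox9 holds GACCTTAA, ribosomal protein genes have many pseudogenes, the Rpl4 locus holds Snord16a, and the loci of Rpl5, Adar and Runx2 overlap Fam69a, Chrnb2 and Supt3h.

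Across the 31 lists tested with camera at the preset correlation, histone, cholesterol and stress genes were higher and interferon-stimulated genes lower at an adjusted p under 0.05. This count of 3 lists higher and 1 lower became 7 and 3 without control replicate 3, 3 and 2 without control replicate 1, and 4 and 2 without Fto siRNA replicate 3. With an estimated correlation camera called 0 lists in either direction, against 11 at an unadjusted p under 0.05 with the preset correlation and 0 with the estimated one. The exact permutation test of list means per library (n = 4 per group) reached its smallest p, 0.0286, in 9 of 31 lists. After adjustment over the lists (adjusted p = 0.0984) it called 0, but no list could pass alone, whatever its effect. Those 9 were higher for histone genes, cell cycle inhibitors, immediate early genes and preadipocyte markers, and lower for interferon-stimulated genes, metalloproteinases, cilium genes, neighbours of Fto and the AlkB family, which holds Fto. The authors' deposited Bonferroni-corrected p-values were read only for genes with a mean FPKM of at least 1. Among these, values under 0.05 were listed for 6 higher and 15 lower genes, and all 21 also passed here in the same direction.

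**Figure D5:**
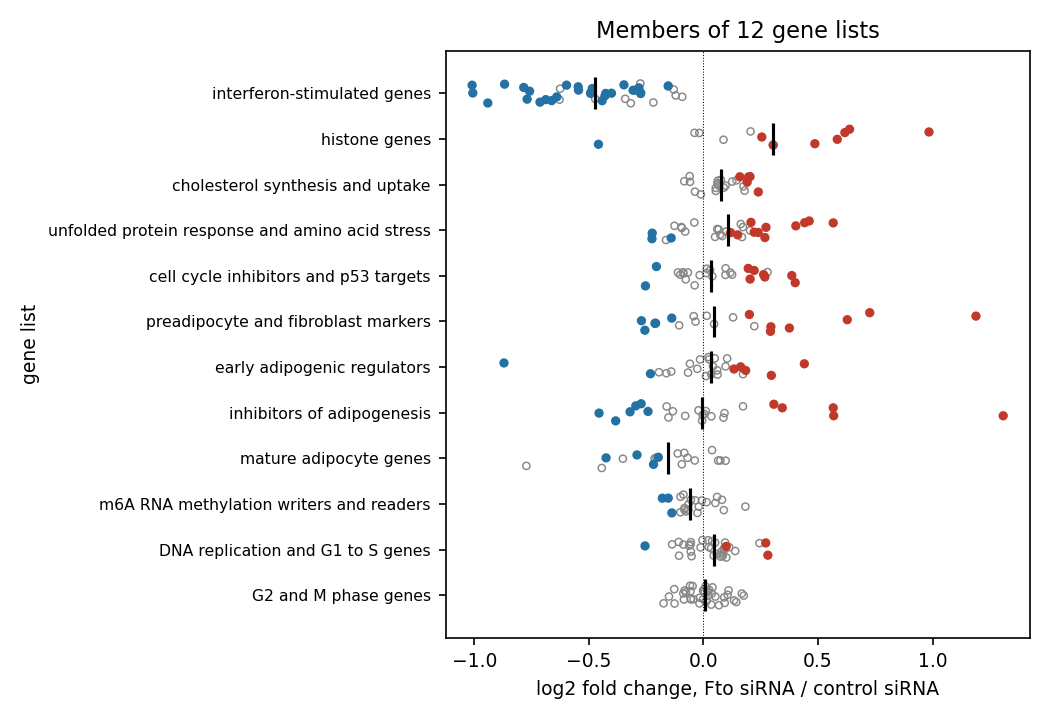
Log2 fold change of Fto siRNA over control siRNA (horizontal axis) of the tested members of 12 gene lists (vertical axis); filled red points rose, filled blue points fell, open points did not pass and black bars are list medians. All 39 interferon-stimulated genes lie below 0 with a median of -0.47, and the histone genes have a median of 0.30.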

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

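The tests of the interferon pattern and of other splits of the libraries were chosen after the results were seen; the values listed last come from a rule set before.

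Interferon-stimulated genes were lower with Fto siRNA, and control replicate 4 stood above the other controls. High levels in that library alone did not account for the list: without it the median of the 39 members was still -0.36 and 39 were lower. Only 3 of the 39 members held GACCTTA or ACCTTAA, so their removal could hardly move the median, which was -0.44 over the other 36. Most of the lower members thus lacked the words, but an indirect effect of carriers on them was not tested. A lower interferon response to Fto siRNA than to control siRNA, through Fto or through the siRNA duplexes themselves, stays open, since each siRNA mix came with 1 group. As a test of the list, 9 of the 35 splits, the real one included, reached the strength of the real one (camera unadjusted p = 3.9e-12, lowest other 5.2e-27). Chance was thus not excluded by camera. The list mean per library parted the groups most in the real split (exact permutation p = 0.0286, adjusted p = 0.0984 over 31 lists).

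The counts of genes were set against the same splits. The 794 rises and 1401 falls were each reached in 1 of 35, the real split, with a highest other of 1 and 1. That is the smallest share these splits allow, so chance was not excluded beyond it. The other splits also mix the groups, which adds the difference between groups to their spread and lowers their counts. The counts of lists did not stand apart from the other splits: a count of 3 higher lists was reached in 26 splits (highest other 8) and of 1 lower list in 30 (highest other 7). The counts of splits here include the real one. Camera compares a list with the other genes, and these held far more calls in the real split than in any other. List tests are thus not on equal terms across splits. A test as strong was found for histone genes in 4 splits (unadjusted p = 1.6e-04, lowest other 1.1e-07), for cholesterol genes in 11 (3.0e-04, lowest other 8.4e-13) and for stress genes in 10 (6.4e-04, lowest other 2.1e-07), so chance was not excluded there by camera. The histone list mean per library also parted the groups most in the real split (exact permutation p = 0.0286, adjusted p = 0.0984), as in 9 of 31 lists. After adjustment 0 lists passed, which no list could do alone.

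Of 328 sets of 4 libraries of a named gene, 21 held a library apart from the other 3 by Dixon's ratio of gap to range (above its critical value), where chance flags about 1 in 20; 20 are given here. In control replicate 3, FPKM stood apart for Calr (1017), Dlk1 (1036), Ebf1 (38.3), Hes1 (14.3), Mmp23 (42.4), Pparg (34.3) and Xpo5 (23.4). In control replicate 1 it did for Amotl2 (83.2), Cdkn1a (99.0), Lrp5 (54.4) and Pfkp (10.9), in control replicate 2 for Rbl2 (22.2), and in control replicate 4 for Gli3 (9.05) and Npnt (2.04). Among Fto siRNA libraries it did for Klf2 in replicate 1 (10.5), Rrm1 in replicate 2 (39.1), H2-K1 in replicate 3 (47.3), and Gli2 (10.4), Lpl (316) and Rhob (54.7) in replicate 4.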

How the results depend on the processing

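The removal of word carriers and of entries without an OK status was chosen after the data were seen. Fto had a log2 fold change of -2.22 to -2.10 and passed under every setting run, and no result reversed. With a minimum fold of 1.2, 33 genes were higher and 56 lower, as a stricter test must give. Without carriers of the words 6 lists were higher; without carriers and control replicate 4, 490 genes were higher, 791 lower and 8 lists higher; the cause was not tested. With an estimated correlation 0 lists were higher and 0 lower, and each of the 4 called lists had an adjusted p of 0.629. The histone list had 0.0507 at a minimum mean FPKM of 5, with fewer genes. Leaving out each library gave 549 to 941 genes higher, 992 to 1432 lower, 3 to 7 lists higher and 1 to 3 lower (7 and 3 without control replicate 3); the cause was not tested. Of 121 named calls, 19 were lost without at least 1 library. No filter ended 13 calls, quantile scaling 6, no trend 5, median-ratio scaling 4, and a minimum mean FPKM of 5, sample weights and the removal of carriers 1 each, all of them among those 19 genes. A replicate block ended 10, with Nfkb1 (adjusted p = 0.0531) outside the 19, the removal of carriers and control replicate 4 ended 13, with Lama4 (0.0511) outside them, and a minimum fold of 1.2 ended 92 of the 121. The other gene results stayed on their side of the threshold in 3152 cases, and 239 were weaker and 25 stronger. Replicate numbers did not pair the libraries (correlations 0.0736, -0.0402, -0.190 and -0.0895, none best with its own number); with a replicate block 628 genes were higher and 1133 lower, with 4 lists higher and 1 lower. Depth limits low genes most. The DESeq2 alternative was not run, since FPKM are not counts.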

Other observations

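The tests of genes with and without the words were chosen after the results were seen, and those of all 7-base words and the neighbourhood were set before. The prenylation test rests on a rise and on words seen in these data, so it was set after those were known.

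Genes whose 3′ UTR holds GACCTTA or ACCTTAA, picked as the words with the lowest z, fell more often than others. The word GACCTTAA was held by 191 genes, of which 87 fell (45.5%, median log2 fold change -0.15), among them Adi1, Thbs2, Marcks and Hadhb. GACCTTA without the last base was held by 393 genes, of which 117 fell (29.8%), and ACCTTAA without the first by 533, of which 102 fell (19.1%). Of 1031 genes with ACCTTA alone 100 fell (9.70%), and of 7486 with none 813 fell (10.9%).

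A candidate explanation of the falls among carriers is silencing through the seed of an Fto siRNA. Of 16178 words searched in the first 5000 bases of each 3′ UTR (the counts above are over whole UTRs), GACCTTA had the lowest z (-16.9, 563 genes) and ACCTTAA the next (-13.3, 747 genes), against a Bonferroni limit of 4.66 and a largest absolute z of 5.34 in 100 shuffles; the words were picked by this z, so the shares of fallen carriers (45.5% for GACCTTAA) and their order are no separate test. Over all words past the limit the prior test did not settle it. Of 7 such words the 2 with the lowest z, GACCTTA and ACCTTAA, lay in the Fto coding sequence, which holds 8.58% of words (hypergeometric p of 0.116). All 7 share bases with GACCTTAA, so they are not the independent draws that this p assumes, and it cannot decide. Of 55976 words of 8 bases GACCTTAA (z -13.8, 182 genes) ranked after TGACCTTA (z -13.9, 237 genes). The Fto coding sequence lacks TGACCTTA, but that word holds GACCTTA, which does occur there. The order of these words thus does not decide for or against an Fto seed. Among 7515 genes without ACCTTA the lowest z of an Fto word was -2.14. This does not exclude a further seed behind the 814 falls there. The adjustment for UTR length and base composition was fitted with the carriers included, which can raise the z of words. The lowest z of any word there was only -2.81. Indirect effects of silenced genes were not tested. An effect of Fto itself on carriers stays untested, and so does the siRNA sequence, which is not given in the sources used here.

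Over the 14 tested genes within 2 Mb of Fto the median log2 fold change was -0.17. Elsewhere, 0.558% of runs of as many neighbouring genes had a median at or below it. The runs overlap one another, so this share is no p-value and cannot decide alone. An effect on the chromosomal neighbourhood may contribute. How it would depend on distance stays open: none of Rpgrip1l (-0.05), Irx3 (-0.21), Aktip (-0.05), Rbl2 (-0.10) and Chd9 (0.12) passed the test, and the 5 genes that fell lie more than 1 Mb downstream, where Ces1f (0.06) and Ces1g (0.10) did not pass. Without Capns2, which lies inside Lpcat2, and the word carriers Mmp2 and Irx3, 6.04% of runs reached the median of the other 11 genes (-0.10), which decides nothing, since all 3 lie below the median of the 14 and their removal had to raise it.

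Klf2 and Rhob rose, as cells with blocked protein prenylation are known to show, and 5 of 23 cholesterol genes rose, though that list was not called with an estimated correlation (adjusted p = 0.629). The hypothesis that an enzyme of prenylation was silenced was not borne out at the mRNA level. Of 9 tested genes the lowest log2 fold change was -0.0628, for Rabggta (limma adjusted p = 0.54), and Fnta rose by 0.15 (adjusted p = 0.029). Protein levels were not measured, and the 3′ UTR of Fntb was not searched. Silencing by the control siRNAs, which would raise genes after Fto siRNA, cannot be told apart from other causes of the rises. The highest z of any word was 4.45 (CTCGCCC), under the limit of 4.66 and under the largest absolute z of 5.34 in 100 shuffles.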
